A study of Mus musculus with 20 samples.

How the data were processed

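Expression and DNA methylation were measured in islets of 10-week-old female NZO/HIBomDife mice, 5 DP and 5 DR samples for RNA sequencing (numbered 16 to 20 and 11 to 15) and 5 DP and 5 DR samples for bisulfite sequencing (lettered A to E in each group). Groups came from the labels. Per the submitters' processing notes, which give no role or order, the tools were Trim Galore 0.4.2, FastQC 0.11.5, HISAT2 2.1.0, Cufflinks 2.2.1 and Bismark, with the genome build GRCm38.p4. Strand and transcript starts were not used here, since no annotation of this build with strand was at hand.

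The authors deposited FPKM per isoform for each RNA sample, as Cufflinks writes them per the file headers, with no read counts. The same deposited tables hold a mean read coverage per isoform, used here only as its ratio to FPKM. The FPKM of a library summed to between 6.557e+05 and 7.31e+06, of which 19.2% (DP 19) to 93.1% (DP 17) fell on isoforms shorter than 200 nt, so sums were not used to scale the main values. Isoforms that Cufflinks marked HIDATA are listed at 0 in the deposited tables. They include Ins1 and Ins2 in all 10 libraries, Ctrb1 in DP 16 and several Amy2a genes in DP 16 and DR 13. For bisulfite samples the authors deposited counts per CpG, the reads covering the site and the methylated reads, per the file headers. A further table deposited by the authors gives p-values per CpG for DP against DR (an unadjusted p, a p combined with neighbouring sites and an fdr), in which -1 marks a site not tested.

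Isoform FPKM were summed per gene, and log2(FPKM + 1) was tested with limma 3.58.1 (R 4.3.3, eBayes with trend, two-sided) over 14854 of 50469 genes, those with a mean of at least 1 FPKM without 5 genes marked HIDATA. All adjusted p-values are Benjamini-Hochberg adjusted, with a threshold of 0.05. A log2 fold change on the log2(FPKM + 1) scale understates the change of low genes. In total 24 gene lists were tested with camera, which compares a list with all other genes, at its preset inter-gene correlation of 0.01, and with an estimated correlation and with fry as alternatives, adjusted over the lists. They cover beta cell identity and insulin secretion, other islet hormone cells, beta cell disallowed genes, dedifferentiation and progenitor genes, unfolded protein response, oxidative stress, cell cycle, primary cilium, glycolysis, respiratory chain, fatty acid and sterol synthesis, fatty acid oxidation and lipid droplets, interferon response, DNA methylation machinery, monogenic and type 2 diabetes genes, imprinted genes, and markers of acinar, duct, endothelial, macrophage and dendritic, lymphocyte, stromal, adipocyte and neural and Schwann cells. The lists, the tests, the main settings and the rule for named genes were chosen before the data were examined.

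Methylated and unmethylated read counts were summed over regions per sample and compared with a quasi-binomial logistic model whose overdispersion was squeezed across regions (limma squeezeVar, F test, two-sided). Gene-end windows run from 1500 bp outside to 500 bp inside both ends of a gene, since strand was not used, gene bodies are the rest of the gene, and tiles are 1000 bp. A region needed 5 CpGs (3 in tiles) and at least 20 reads in every sample. The lowest-covered sample, DR C, covered 32.3% of autosomal CpGs, which limits how many regions could be tested. edgeR 4.0.16 (quasi-likelihood) and limma on log2 ratios served as alternatives. Global methylation was compared with an exact permutation test over 252 arrangements, whose smallest two-sided p is 0.00794. Coordinates are those of the deposited files, 1-based for genes. Reads of 1 DNA molecule are not independent across CpGs, so read counts overstate precision.

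Named genes were up to 12 with the largest rise and 12 with the largest fall among genes past the threshold whose groups did not overlap, without clone or prediction names, all passing members of a list when 6 or fewer and otherwise the 3 largest rises and 3 largest falls (the 2 of smallest p if none passed), and Ins1, Ins2, Gcg, Sst, Ppy, Pdx1, Mafa, Slc2a2, Aldh1a3, Txnip, Prss2, Try4, Dnmt1, Dnmt3a and Tet1. For methylation they were up to 8 gene ends or bodies and 5 tiles per direction, or the 4 of smallest p if none passed, and for the authors' regions the 5 per direction with most sites. The other trypsinogen genes were named after their values were seen. Some genes that meet these rules are not reported here.

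The expression test was tested on simulated data for DP against DR over 14854 genes, and recovered 37.3% of 67 genes changed 1.5-fold, 76.1% of 67 changed 2-fold and 91% of 67 changed 4-fold, with 8 false calls. Simulated genes varied independently of each other and no simulated library stood apart, unlike in the real data, so these rates and false calls may not carry over. Simulated gene bodies (20721) that differed by 5, 10 and 20 percentage points were recovered in 1.49%, 44.8% and 85.1% of 67 cases each, with 7 false calls, simulated gene-end windows (17193) in 0%, 1.49% and 28.4%, with 1, and simulated tiles (21418) in 0%, 5.97% and 43.3%, with 2. These changes were placed only in regions of intermediate methylation, so the rates do not describe regions of high or low methylation. Alternatives covered the pseudocount, the filter on low FPKM, the scaling, single isoforms, array weights, the acinar list mean as a covariate, the coverage minimum, window and tile sizes, the test, a global methylation offset, the sample letter as a block and leaving out each sample in turn. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for the rest, and matplotlib 3.10.9 for figures.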

Results

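NZO/HIBomDife is an inbred strain of obese mice in which part of the animals become diabetic. Islets of Langerhans, the clusters of hormone-secreting cells in the pancreas, came from 10-week-old females classed as diabetes-prone (DP) or diabetes-resistant (DR), the healthy control group. RNA of 100 islets per sample was sequenced in 5 DP and 5 DR samples, and DNA was sequenced after bisulfite treatment, which reads out cytosine methylation, in 5 DP and 5 DR samples. The submitters' design text speaks of 4 and 5 RNA samples, and 5 and 5 were analysed here. The comparisons address which differences in expression and DNA methylation islets carry before diabetes begins. The labels say that DNA came from each pool and do not tie the samples to animals, so p-values measure only the spread between these samples, which may be technical. Expression was deposited as FPKM without read counts, so RNA depth is unknown. Read coverage per FPKM unit, which tracks depth, ran from 8.48 (DP 17) to 16.04 (DP 16) in DP and from 6.73 (DR 11) to 12.45 (DR 13) in DR. Isoforms above 0 FPKM numbered 85271 to 87929 in DP libraries and 80506 to 84144 in DR libraries, without overlap. Whether a group difference in depth affects genes of low FPKM was not tested. Bisulfite reads covering CpGs ranged from 11986363 in DR C to 80106057 in DR D, a mean of 0.554 and 3.70 reads per autosomal CpG, and the other 8 samples lay between 1.38 and 3.25.

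DP islets contained more transcript of 2 gut hormones than DR islets. Cck (cholecystokinin) measured 53.8 ± 29.5 FPKM in DP and 1.63 ± 0.754 in DR (SD, n = 5 each), a log2 fold change of 4.19 (SE 0.44; limma, Benjamini-Hochberg adjusted p = 0.00222). Gast (gastrin) measured 14.7 ± 6.16 and 0.98 ± 0.677 FPKM, a log2 fold change of 2.96 (SE 0.31; limma adjusted p = 0.00222). Cck lies on chromosome 9 at 121489824-121495694 and Gast on chromosome 11 at 100334407-100336996 (GRCm38.p4). Csn3, a milk casein, rose by 3.42 on the log2 scale, from 0.271 ± 0.116 to 14.9 ± 9.05 FPKM (limma adjusted p = 0.00359). Prss1 and Prss3, which encode trypsinogens, had the largest rises apart from genes with clone or prediction names, 6.76 and 6.71, and belong to a family of near-identical copies that makes their level uncertain. Lcn2 (2.68), which carries bacterial iron chelators, the acute-phase gene Saa3 (2.08), the water channel Aqp1 (2.24), Wfdc18 (2.14), Tm4sf20 (2.11) and the matrix genes Col1a1 (2.08) and Dcn (2.04) also rose. With libraries left out 1 at a time, the highest limma adjusted p was 0.0108 for Cck and for Gast, while Lcn2 reached 0.0515 without DP 20, Aqp1 0.0549 without DR 14, Dcn 0.0879 without DR 14 and Saa3 0.114 without DP 20.

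The largest falls in DP islets belonged to single genes of differing functions. T2 had the largest named fall, 1.45 ± 0.914 FPKM in DP against 7.99 ± 1.29 in DR, a log2 fold change of -1.94 (limma adjusted p = 0.00383). Gad1, which makes GABA from glutamate, fell from 16.1 ± 1.40 to 5.08 ± 3.25 FPKM, a log2 fold change of -1.67 (SE 0.33; limma adjusted p = 0.0154). Cntfr, the receptor of ciliary neurotrophic factor, fell from 64.7 ± 7.34 to 24.6 ± 9.31 FPKM (-1.43; limma adjusted p = 0.00702). Cyp4f39 (-1.86), Mreg (-1.54), the inward rectifier channel Kcnj12 (-1.46), the calcium-binding genes Cib3 (-1.44) and Cabp7 (-1.27), the methyltransferase Gnmt (-1.26), the fucosyltransferase Fut1 (-1.25) and Ogdhl (-1.24) fell as well. Without DP 20, Cib3 had a limma adjusted p of 0.0682 and Gnmt of 0.107, and the other falls named here stayed at or below 0.0447, apart from Cabp7 at 0.0486.

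**Figure D1:**
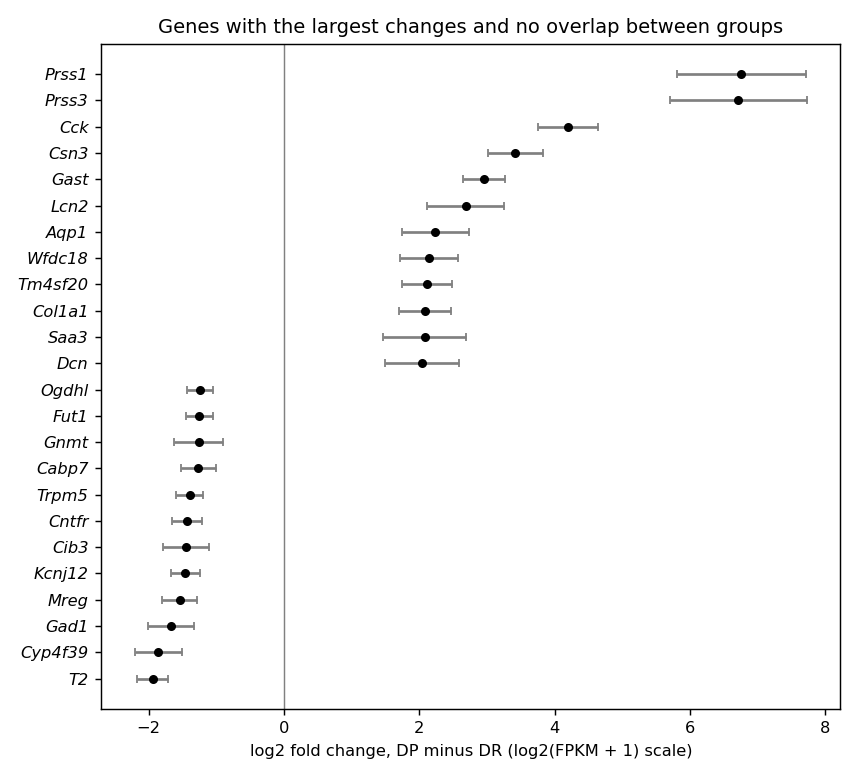
Log2 fold change, DP minus DR on the log2(FPKM + 1) scale, of the 12 largest rises and 12 largest falls among genes whose 5 DP and 5 DR libraries did not overlap, without clone or prediction names, with bars of 1 SE. Rises reach from 2.04 (Dcn) to 6.76 (Prss1) and falls from -1.24 (Ogdhl) to -1.94 (T2).

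In all, 2116 of 14854 tested genes changed, 1234 higher and 882 lower in DP (limma, Benjamini-Hochberg adjusted p under 0.05). The groups did not overlap for 2268 tested genes, 15.3% against the 0.794% that chance gives, and 1676 of these were among the 2116. The split between higher and lower depended on scaling: 1143 to 1319 with median-of-ratios scaling, 799 to 1616 with quantile normalization and 945 to 1250 with the trend over transcript length removed. Rescaling each library to the same sum, which put the median log2 fold change of all genes at -0.455, gave 47 calls, 27 of them among the 2116. The same rescaling over genes of at least 200 nt gave 1134, 977 of them among the 2116. Without single libraries the count was 3466 (DP 16), 871 (DP 19), 734 (DP 20), 1213 (DR 11), 1020 (DR 12), 1143 (DR 13), 760 (DR 14) and 987 (DR 15), and 660 genes passed in the full set and in all 10 such fits. DP 16 stood apart on the first principal component, at -102.68 against -40.32 to 50.85 in the other 9 libraries.

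Genes that define beta cells and their glucose sensing were lower in DP islets. Slc2a2, which encodes the beta cell glucose transporter GLUT2 (chromosome 3, 28697903-28731359), measured 99.6 ± 43.3 FPKM in DP and 219 ± 18.3 in DR, a log2 fold change of -1.23 (SE 0.26; limma adjusted p = 0.0169). Trpm5, a calcium-activated cation channel (-1.39), Ucn3, a marker of mature beta cells (-1.02), the granule zinc transporter Slc30a8 (-1.01), the gap junction gene Gjd2 (-0.82) and the transcription factor Isl1 (-0.48) also fell, 6 of 32 tested members of the beta cell list, 12 when adjusted over the list alone, with none higher. As a set the list was lower at the preset correlation (camera, Benjamini-Hochberg adjusted p = 9.86e-06), but not with an estimated correlation (camera adjusted p = 0.595) or with fry (adjusted p = 0.141). The list averaged 7.004 ± 0.445 in DP and 7.44 ± 0.052 in DR (mean log2(FPKM + 1), n = 5 each), with DP 16, highest in stromal markers (5.83), at 6.24 and the other DP libraries at 7.06 to 7.37. The transcription factors Pdx1 (-0.40, limma adjusted p = 0.148) and Mafa (-0.63, 0.233) did not pass. Ins1 and Ins2 were listed at 0 in every library, marked by Cufflinks as having too many reads to estimate, and give no insulin value. Trpm5 and Slc2a2 passed in each fit without 1 library, with limma adjusted p up to 0.0207 and 0.0496, while Ucn3 reached 0.0532 (without DP 20), Gjd2 0.0536 (DP 19), Slc30a8 0.0549 (DR 14) and Isl1 0.0764 (DR 14).

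The hormones of the other islet cells did not pass. Sst (somatostatin, -0.51, limma adjusted p = 0.0699), Gcg (glucagon, -0.40, 0.236) and Ppy (pancreatic polypeptide, 0.16, 0.624) missed the threshold with all libraries. Sst passed as lower without DP 16 (0.0202), without DP 18 (0.045), without DP 16 and with the acinar covariate (0.00807) and with the trend over transcript length removed (0.0285). In the list of other islet hormone cells, Ttr (1.04) and Gc (0.74), both abundant in alpha cells, rose and Hadh (-0.78) and Peg10 (-0.38) fell, of 15 tested. Adjusted over the list alone, 2 rose and 6 fell. The set did not pass (camera adjusted p = 0.0567), but did as lower without DP 18 (0.018), without DR 13 (0.0151), without DP 16 and with the acinar covariate (0.0378) and with the length trend removed (0.0394). Without DR 14 the limma adjusted p was 0.052 for Gc, 0.0726 for Hadh and 0.121 for Peg10, and without DP 20 it was 0.0778 for Ttr, which had 0.102 with quantile normalization.

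Some genes that beta cells normally keep silent or use in immature states were higher. Aldh1a3, a marker of dedifferentiated beta cells, measured 35.9 ± 12.04 FPKM in DP and 16.7 ± 4.63 in DR (1.03; SE 0.28; limma adjusted p = 0.0377). In the dedifferentiation and progenitor list 6 of 13 members rose, among them Cck, Gast, Vim (1.54) and Aldh1a3, and Fev (-0.65), a serotonergic transcription factor, fell, 8 and 1 when adjusted over the list alone (camera adjusted p = 0.00782; adjusted p = 0.595 with an estimated correlation; fry 0.00623). Of the beta cell disallowed list, Pdgfra (1.16), a receptor also typical of fibroblasts, and Oat (0.85) rose among 17 tested, 0 when adjusted over the list alone (camera adjusted p = 0.00143; adjusted p = 0.595 with an estimated correlation). The disallowed list measured 4.30 in DP 16, against 2.39 to 3.10 in the other DP libraries and 2.29 ± 0.312 in DR, and DP 16 was also highest in the stromal and macrophage lists. Vim and Pdgfra are stromal genes as well, and all 18 stromal markers rose. Leaving out DP 20 took Aldh1a3 to a limma adjusted p of 0.0866, Vim to 0.0726 and Oat to 0.108, leaving out DR 15 took Pdgfra to 0.0829 and leaving out DR 14 took Fev to 0.052.

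Cell cycle genes rose together. Of 22 tested members 19 rose and none fell, 21 when adjusted over the list alone, among them the survivin gene Birc5 (1.17), the mitotic kinase Cdk1 (1.09) and the topoisomerase Top2a (1.01), which went from 1.83 ± 0.469 to 4.68 ± 0.73 FPKM (n = 5 each; limma adjusted p = 0.00467). The set was higher (camera adjusted p = 1.63e-11; adjusted p = 0.595 with an estimated correlation; fry 0.00247), and the list mean was 2.30 ± 0.169 in DP and 1.59 ± 0.161 in DR. Stromal (4.88 and 3.42) and macrophage markers (4.54 and 3.14) were higher in DP libraries too. Cdk1 had a limma adjusted p of 0.0634 without DP 20.

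Genes of protein folding in the endoplasmic reticulum rose. Derl3 (1.37), which takes part in degrading misfolded proteins, Creld2 (1.30) and the chaperone Hspa5 (0.80; 1218 ± 388 FPKM in DP, 665 ± 59.6 in DR) were among 7 of 25 members of the unfolded protein response list that rose, while Asns, an amino acid response gene, fell (-0.39). Adjusted over the list alone, 12 rose and 2 fell (camera adjusted p = 0.00937; adjusted p = 0.595 with an estimated correlation). DP 16 measured 6.49 on this list, within the DR range of 6.48 to 6.58, and the other 4 DP libraries 6.95 to 7.15. Txnip, a thioredoxin inhibitor induced by glucose, rose from 87.1 ± 18.9 to 278 ± 110 FPKM (1.58; SE 0.28; limma adjusted p = 0.0107). In the oxidative stress list 4 of 20 rose, including Txn1 (0.76) and Sod1 (0.33), and Nqo1 (-1.16) and the metallothioneins Mt2 (-0.80) and Mt1 (-0.76) fell, 5 and 3 when adjusted over the list alone. The set did not pass (camera adjusted p = 0.911). Leaving out DP 20 took the limma adjusted p of Hspa5 to 0.108, of Asns to 0.0717 and of Sod1 to 0.0708. Leaving out DP 19 took that of Mt2 to 0.108 and of Mt1 to 0.0558. Sod1 was at 0.10 (limma adjusted p = 0.239) with the length trend removed, and Hspa5 had 0.174 with quantile normalization.

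Connective tissue transcripts were higher in DP islets in every member measured. All 18 stromal markers rose, and all 18 when adjusted over the list alone, with Col1a1 at 29.7 ± 18.5 FPKM in DP and 5.35 ± 1.27 in DR (2.08; SE 0.38; limma adjusted p = 0.011), Dcn at 2.04 and Col3a1 at 1.95 on the log2 scale. The set was higher (camera adjusted p = 4.4e-11; adjusted p = 0.595 with an estimated correlation; fry 0.007), with a list mean of 4.88 ± 0.628 against 3.42 ± 0.235. Among duct markers the secreted phosphoprotein Spp1 (2.21) and the keratin Krt19 (1.67) rose, 2 of 11 and 4 when adjusted over the list alone (camera adjusted p = 0.00501; adjusted p = 0.595 with an estimated correlation). The stromal mean was 5.83 in DP 16 and 4.10 to 4.94 in the other DP libraries, and the duct mean 5.61 in DP 16 and 3.98 to 4.52 in the others. Endothelial markers did not pass as a set (camera adjusted p = 0.803; 4.34 ± 0.129 against 4.33 ± 0.111): Sox17 rose (0.70), and Esm1 (-1.10) and the VEGF receptors Flt1 (-0.35) and Kdr (-0.45) fell, of 16 tested, 3 and 3 when adjusted over the list alone. Without DR 14 the limma adjusted p of Spp1 was 0.0986 and that of Krt19 0.116, without DP 20 those of Kdr and Flt1 were 0.0784 and 0.0658 and without DP 19 that of Sox17 was 0.0882.

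Immune cell transcripts were higher in DP, with a wide spread between DP libraries. The complement genes C1qa (1.38), C1qb (1.74) and C1qc (1.86) and the lysozyme Lyz2 (2.95) rose, 4 of 19 macrophage and dendritic markers and 16 when adjusted over the list alone. C1qa measured 92.9 ± 28.1 FPKM in DP and 33.8 ± 3.50 in DR (limma adjusted p = 0.00478), and Lyz2 shares sequence with Lyz1, which makes its level uncertain. The set was higher (camera adjusted p = 9.86e-06; adjusted p = 0.595 with an estimated correlation), with a mean of 4.54 ± 1.05 against 3.14 ± 0.461 and with DP 16 at 6.09. No lymphocyte marker passed of 15 tested by limma, and 0 when adjusted over the list alone. Ltb (2.03, limma adjusted p = 0.159) and Ighm (3.30, 0.163) had the smallest p. The lymphocyte set passed as higher (camera adjusted p = 0.00937; adjusted p = 0.621 with an estimated correlation) but not without DP 16 (0.202) or with the acinar covariate (0.058), where its mean log2 fold change went from 1.66 to 0.89. In the interferon list Usp18 (0.44) and Ifi27 (0.56) rose and the antiviral gene Mx1 fell (-1.03) of 23 tested, 2 and 1 when adjusted over the list alone. The set passed as higher (camera adjusted p = 0.00664; adjusted p = 0.621 with an estimated correlation) but not without DP 16 (0.081) or with the acinar covariate (0.058), where the mean went from 0.47 to 0.25. Without DR 14 the limma adjusted p was 0.0841 for C1qb, 0.0736 for C1qc and 0.105 for Lyz2, without DP 20 it was 0.0562 for Ifi27 and without DP 19 it was 0.0911 for Mx1.

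**Figure D2:**
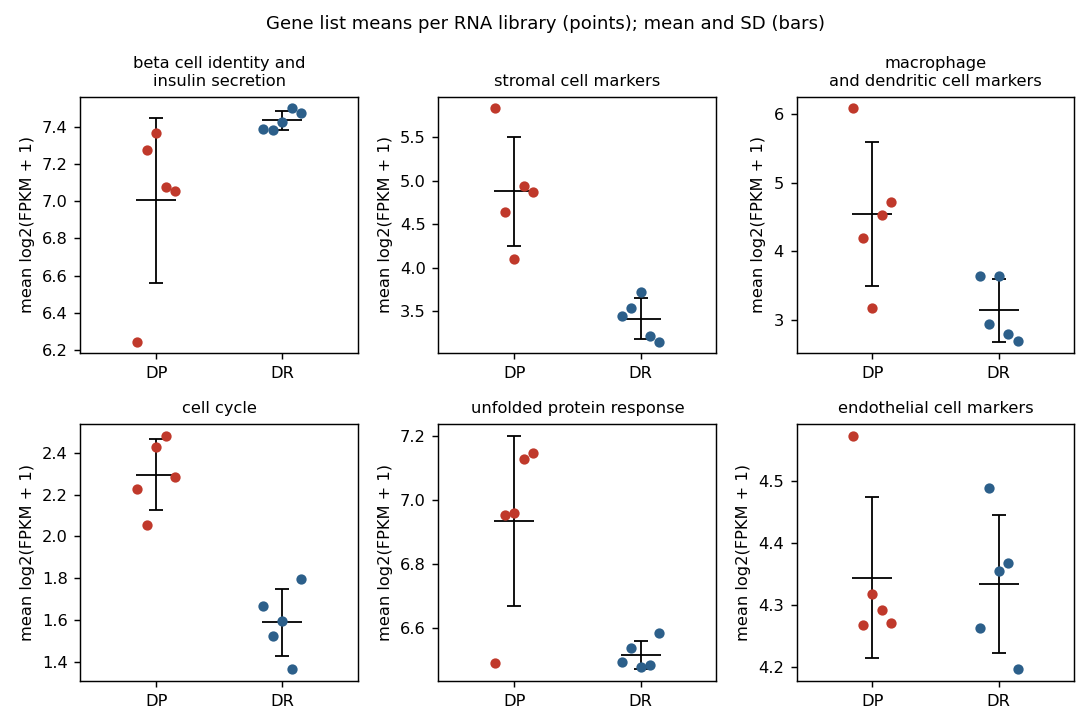
Mean log2(FPKM + 1) of 6 gene lists in each RNA library (points), with the group mean and SD (bars, n = 5), on axes that do not start at 0. The beta cell list lies lower in all 5 DP libraries and lowest in DP 16 (6.24), the stromal and cell cycle lists lie higher in all 5, and the endothelial list overlaps (4.34 and 4.33).

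Exocrine transcripts varied between libraries more than between groups, apart from 1 cluster of trypsinogen genes. The acinar list averaged 8.74 ± 1.62 in DP and 7.91 ± 1.02 in DR, with DP 16 at 11.3 (camera adjusted p = 0.282), and Prss1 was the only 1 of 23 members to rise, 1 also when adjusted over the list alone. The set passed as higher without DP 18 (camera adjusted p = 0.018) and without DR 13 (0.0355). Without DP 16 its mean log2 fold change went from 0.83 to 0.20 (camera adjusted p = 0.678). In the trypsinogen cluster on chromosome 6, between 40964754 and 41525079, 6 genes rose: 1810009J06Rik (7.45), Gm2663 (7.56), Prss3 (6.71), Gm5771 (7.57), Gm10334 (7.43) and Prss1, from 3.81 ± 2.71 to 1175 ± 1988 FPKM (6.76; SE 0.95; limma adjusted p = 0.00537). Their neighbours 2210010C04Rik (0.59), Try4 (1.59, limma adjusted p = 0.215), Try5 (1.83), Try10 (1.43) and Prss2 (0.15, limma adjusted p = 0.908) did not pass. With the acinar list mean as a covariate Prss2 was lower in DP (-0.69, limma adjusted p = 0.00551) and Try4 higher (0.68, 0.01). That mean itself includes Prss1, Prss2 and Try4. Genes of this cluster are near-identical copies whose reads can be assigned to more than 1 of them, so single levels are uncertain.

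**Figure D3:**
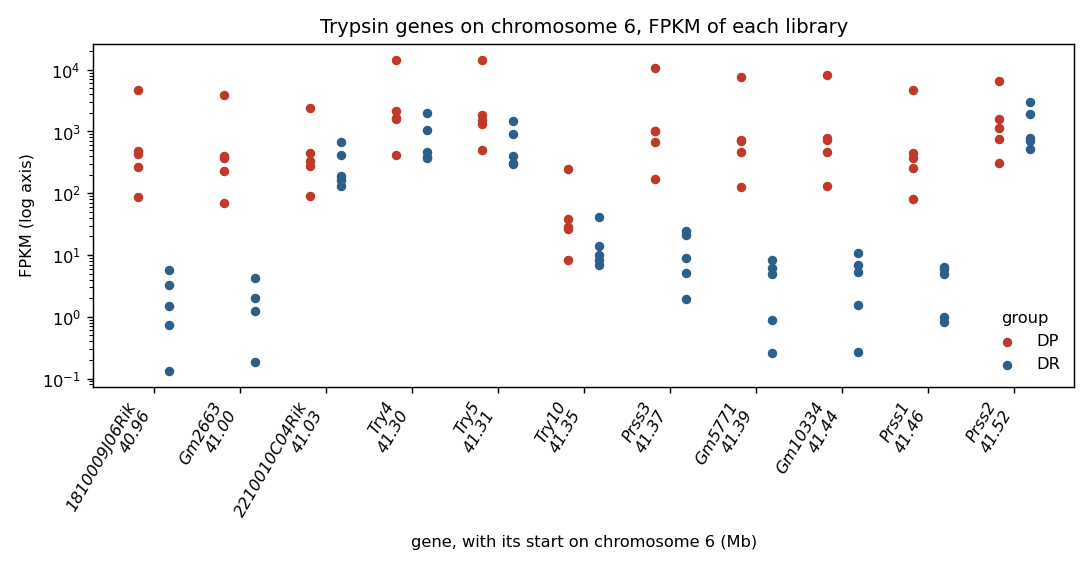
FPKM of the 11 genes of the trypsinogen cluster in each library, on a log axis, in order of position on chromosome 6; a library at 0 is not drawn (Gm2663 in DR 14). For Prss1 the DP libraries lie between 79.6 and 4723 FPKM and the DR libraries between 0.807 and 6.47, while for Prss2 the groups overlap (311 to 6548 in DP, 524 to 2996 in DR).

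Some genes of lipid synthesis were lower in DP islets and some of respiration higher. Srebf1, a transcription factor of lipid synthesis (-0.50), the fatty acid synthase Fasn (-0.39) and the desaturase Scd2 (-0.51) were among 4 of 22 members that fell, 5 when adjusted over the list alone (camera adjusted p = 0.00201; adjusted p = 0.595 with an estimated correlation). Of 33 respiratory chain genes 9 rose, led by the complex I subunits Ndufa1 (1.23) and Ndufa2 (0.59) and by Cox7c (0.55), 10 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0134; adjusted p = 0.595 with an estimated correlation; fry 0.0261). The respiratory chain set did not pass without DP 18 (camera adjusted p = 0.0659) or with the trend over transcript length removed (0.569), which left Ndufa2 and Cox7c at 0.34 each. Neither glycolysis (Eno1 0.54 and Bpgm 0.41 up, Aldoa -0.33; of 15; 3 and 3 adjusted over the list alone) nor fatty acid oxidation (Cpt2 -0.35; of 17; 0 and 2 adjusted over the list alone) passed, both with a camera adjusted p of 0.803. The mean log2 fold change of the fatty acid oxidation list was 0.20 while its test pointed down, and that of glycolysis 0.01 with its test down. Without DP 20 the limma adjusted p was 0.114 for Scd2 and 0.0582 for Aldoa, without DP 19 it was 0.0669 for Fasn and 0.0677 for Eno1 and without DR 14 it was 0.097 for Bpgm.

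Primary cilium genes were slightly lower. Bbs1 (-0.45), Ift140 (-0.30), Ift74 (-0.30), Ift88 (-0.30) and Tulp3 (-0.26) fell and Ift20 rose (0.57), of 29 tested, and the same counts held adjusted over the list alone (camera adjusted p = 0.00143; adjusted p = 0.595 with an estimated correlation). Of the DNA methylation machinery, Uhrf1 (0.66), which guides maintenance methylation in dividing cells, rose and the methyl-CpG reader Mbd2 (-0.38) fell, of 15 tested, 1 and 2 adjusted over the list alone (camera adjusted p = 0.282). The methyltransferases Dnmt1 (0.17, limma adjusted p = 0.0937) and Dnmt3a (-0.15, 0.402) and the demethylating enzyme Tet1 (-0.04, 0.84) did not pass. Among imprinted genes Mest rose (0.65) and Rasgrf1 (-0.66), Peg13 (-0.48), Peg3 (-0.67) and Peg10 (-0.38) fell, of 23 tested, 2 and 6 adjusted over the list alone (camera adjusted p = 0.282; median 0.03, test down). Among monogenic and type 2 diabetes genes Adamts9 rose (0.75) and Pparg (-0.59), Prox1 (-0.37) and Glis3 (-0.26) fell, of 27 tested, 1 and 4 adjusted over the list alone (camera adjusted p = 0.282; mean 0.03, test down). Of neural and Schwann cell markers Ngfr rose (0.71; 1 of 7 and 1 adjusted over the list alone; camera adjusted p = 0.451). Of adipocyte markers 2 were tested by limma and 0 passed, Fabp4 (1.06, adjusted p = 0.0717) and Car3 (-0.74, 0.486), with 1 higher when adjusted over the list alone (camera adjusted p = 0.803). Leaving out DP 20 took the limma adjusted p of Tulp3 to 0.108 and of Mbd2 to 0.0597. Leaving out DP 19 took that of Ift74 to 0.052, of Prox1 to 0.0596 and of Peg13 to 0.085. Leaving out DR 14 took that of Ift88 to 0.0862, of Ift20 to 0.0633, of Uhrf1 to 0.0891, of Mest to 0.0574, of Rasgrf1 to 0.0672, of Peg3 to 0.106 and of Glis3 to 0.0973. Quantile normalization left Uhrf1 at 0.32 (limma adjusted p = 0.261) and Ngfr at 0.50 (0.0725), and Glis3 had 0.145 with the length trend removed.

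Across the 24 lists, 13 passed camera with its preset correlation, 10 higher and 3 lower, 0 passed with an estimated correlation (adjusted p from 0.595 to 0.906), and 4 passed fry, which tests direction within a list without comparing it with other genes. These 4 were the cell cycle, stromal, dedifferentiation and progenitor, and respiratory chain lists, and all others had a fry adjusted p of 0.0575 or more. Estimated correlations ran from -0.00927 (oxidative stress) to 0.967 (acinar), against the preset 0.01. They were 0.79 for the beta cell list and 0.849 for the stromal list.

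CpG methylation over the whole genome differed by less than the spread between samples. DP islets averaged 74.9% ± 1.32 and DR islets 74.8% ± 1.11 methylated reads (SD, n = 5 each), a difference of 0.052 percentage points (exact two-sided permutation p = 0.929; smallest possible 0.00794). X chromosome CpGs were 70.2% ± 1.98 and 69.8% ± 1.37 methylated (exact permutation p = 0.698), and mitochondrial CpGs 0.382% and 0.377%. The difference was -0.378 without DP B, -0.135 without DP D, -0.155 without DR A, -0.159 without DR B, -0.011 without DR E and 0.518 without DR C.

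No gene-end window, the stretch around either end of a gene and so around its promoter, changed methylation past adjustment. Of 17193 windows tested with the quasi-binomial model 0 passed, 1101 had an unadjusted p under 0.05 (6.4%), and edgeR and limma also called 0, with 762 and 881 at an unadjusted p under 0.05. The smallest p belonged to Itpr3, an inositol trisphosphate receptor that releases calcium from the endoplasmic reticulum (chromosome 17, 27057304-27122223), with 39.1% ± 10.0 in DP and 14.4% ± 3.90 in DR (n = 5 each; quasi-binomial adjusted p = 0.447; at least 33 reads per sample). Pld3 (32.2% ± 8.91 and 11.3% ± 3.47), Tmem200a (76.8% ± 4.55 and 60.02% ± 3.21) and Ppp1r3e, a glycogen regulator (48.9% ± 11.9 and 25.7% ± 7.66), followed, with the same adjusted p and lowest coverages of 26, 56 and 21 reads. For Itpr3, Pld3 and Tmem200a all 5 DP samples lay above all 5 DR samples. Windows of 500 bp on each side gave 1 call among 4782, and leaving out DR A gave 1. In simulated data, 28.4% of windows that differed by 20 percentage points and 1.49% of those that differed by 10 were recovered. The simulated changes lay only in windows of intermediate methylation, so differences of 20 points or less there would mostly be missed at this depth.

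Methylation of 3 gene bodies differed. Nell1 (chromosome 7, 49974864-50866608) was less methylated in DP, 80.7% ± 0.187 against 83.2% ± 0.438 (n = 5 each; quasi-binomial model, Benjamini-Hochberg adjusted p = 0.00023), as was Ptprt, a receptor tyrosine phosphatase (chromosome 2, 161521990-162661147), 81.6% ± 0.255 against 83.9% ± 0.503 (adjusted p = 0.00026). Ebf3, a transcription factor gene (chromosome 7, 137193673-137314445), was more methylated, 67.5% ± 1.51 against 63.4% ± 0.426 (adjusted p = 0.0495). The groups did not overlap for any of the 3, and coverage was at least 3443, 4100 and 612 reads per sample. Among 20721 bodies tested, 1584 had an unadjusted p under 0.05, edgeR and limma called 0, with 1009 and 955 at an unadjusted p under 0.05, and 34 were called with the sample's global level as an offset, 4 higher and 30 lower. Ebf3 was no longer called without DP B, DP D, DP E, DR A, DR D or DR E or with at least 10 reads, where 0 bodies were higher and 2 or 3 lower.

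Among 1 kb tiles 3 were more methylated in DP and none less. The tile at 107403001-107404000 on chromosome 11, within Pitpnc1, a phosphatidylinositol transfer protein gene, measured 38.6% ± 9.48 against 17.8% ± 3.03 (n = 5 each; quasi-binomial adjusted p = 0.0407). The tile at 128222001-128223000 on chromosome 3, within D030025E07Rik, measured 49.4% ± 8.68 against 27.9% ± 7.62 (adjusted p = 0.0475), and that at 91552001-91553000 on chromosome 12, nearest to Gtf2a1, 77.5% ± 2.69 against 58.0% ± 6.12 (adjusted p = 0.0496). These were 3 of 21418 tiles with enough coverage, of which 1327 had an unadjusted p under 0.05. The 21418 came from 1298524 tiles with at least 3 CpGs and at least 10 reads in most samples, not from the whole genome. The calls ended with at least 50 reads per sample (0 of 972), in limma (0), and without any 1 of DP A, DP B, DP D, DR A, DR B, DR D or DR E (0 each). There were 1 without DP E, 5 without DP C, 21 without DR C, 9 in 5 kb tiles and 10 with at least 10 reads.

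**Figure D4:**
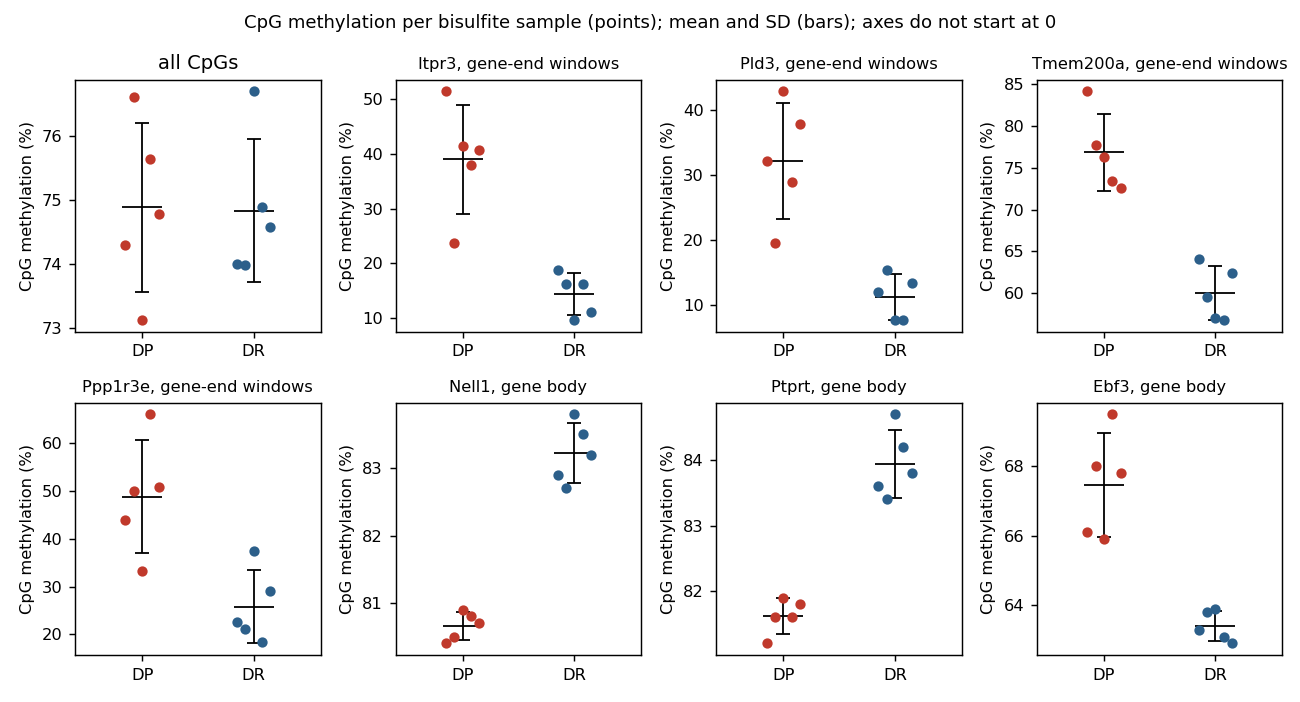
Percent CpG methylation in each bisulfite sample (points), with the group mean and SD (bars, n = 5), for all CpGs, the 4 gene-end windows of smallest p and the 3 gene bodies that differed, on axes that do not start at 0. Levels over all CpGs overlap (74.9% and 74.8%), and the Nell1 and Ptprt gene bodies lie lower in all 5 DP samples (80.7% and 81.6%) than in all 5 DR samples (83.2% and 83.9%).

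The authors' deposited table of single-site p-values marked more sites as more methylated in DP than as less. Of 16370192 tested CpGs, 2580 had a deposited fdr under 0.05, 1977 with a higher and 599 with a lower share of methylated reads in DP, and 862033 (5.27%) had a deposited unadjusted p under 0.05. Joined within 500 bp, the sites formed 338 regions of at least 3 sites, 273 higher and 65 lower in DP, with a median absolute difference of 42.8 percentage points and a median length of 139.5 bp. Regions with most sites that were higher lay in Mpp7, a cell polarity gene (chromosome 18, 7609151-7609577, 44 sites, 65.9% of 425 DP reads and 31.7% of 180 DR reads in the authors' deposited table), Ptprt (chromosome 2, 162485693-162485894, 70.3% and 35.5%), Gnas, an imprinted locus for a G protein subunit (chromosome 2, 174300445-174300808, 77.2% and 32.5%), Ubqln2 (chromosome X, 153498437-153498826, 58.6% and 14.1%) and Ccm2l (chromosome 2, 153071815-153072109, 84.0% and 2.6%). Those that were lower lay in the transcription factor gene Foxo6 (chromosome 4, 120267990-120269249, 45.6% and 79.3%), 7867 bp from Gm15569 (chromosome 15, 86195019-86195295, 47.1% and 87.9%), in Proser2 (chromosome 2, 6100607-6100756, 0.0% of 22 reads and 70.2% of 47), in Gm6051 (chromosome 5, 76060603-76060797, 66.4% and 96.6%) and in Paupar and Pax6os1, beside the islet transcription factor gene Pax6 (chromosome 2, 105660037-105660231, 5.9% and 67.3%). Coverage was thin: 127 of the 338 regions had reads in every sample, and in 39 of these the groups did not overlap. In Ccm2l the methylated DP reads came from DP D alone (91.3%), and DP B and DP E had 0%. In Mpp7 the groups overlapped, with DR A at 31.0%, DR D at 100% and DR E at 0% against 37.1% to 100% in DP. With a deposited fdr under 0.01 the regions numbered 102, and with at least 5 sites 223.

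No gene passed adjustment in both expression and methylation, where few regions passed in methylation at all. Of 11145 genes tested for expression and gene body methylation, 1567 changed in expression, 2 in methylation and 0 in both, with 0.3 expected (Fisher's exact p = 1.0). Of 7016 with gene-end windows 0 changed in methylation. With so few methylation calls an overlap could hardly be seen, so this count does not tell whether expression and methylation changed together. At an unadjusted p under 0.05 in both measures, 383 genes overlapped for bodies, against 338.1 expected (Fisher's exact odds ratio 1.24, p = 0.00177), and 218 for gene-end windows (Fisher's exact odds ratio 1.15, p = 0.113). Together these were 589 genes. Fisher's test takes genes as independent, which they are not, so its p overstates the evidence. Expression and methylation moved in opposite directions in 224 of the 383 and in 114 of the 218. For bodies 162 were lower in expression and more methylated, 62 the reverse, 105 higher in both and 54 lower in both. For gene-end windows these counts were 84, 30, 78 and 26. More genes gained than lost methylation whichever way expression went, and the opposite counts were not compared with chance. Across genes, which are not independent replicates, the log2 fold change and the methylation difference correlated weakly in a family of 4 relations: Spearman's rho was -0.034 for bodies (exact p over the 252 arrangements of the bisulfite samples 0.0714), -0.031 for gene-end windows (0.119), -0.044 for windows of 500 bp on each side (0.0476) and 0.016 for the less methylated gene end (0.357). RNA and bisulfite samples were not matched, so only group differences were joined. Genes expressed below 1 FPKM had a median methylation of 53.3% in DP and 50.8% in DR at their less methylated end, and genes of 50 FPKM and over 15.5% and 14.5%.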

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

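The counts of other sample splits, the test of reads shared between neighbouring trypsinogen genes as a set, and the fits with the acinar covariate, an estimated correlation and fry were planned, while the use of these fits to weigh explanations, the removal of the length trend and the other tests in this part were chosen after the results were seen.

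The 10 RNA libraries can be divided 5 against 5 in 126 ways, of which 100 were drawn, as for the bisulfite samples. Chance in how these 10 libraries fell into groups can be excluded for the 2116 genes changed in expression. Only the real split, 1 of 100, gave as many, and the highest other split gave 20. The labels do not tie the libraries to animals, so the splits cannot tell whether other DP and DR mice would differ alike. Chance cannot be excluded for the 13 lists past camera, since 5 of 100 splits gave as many and the highest other also gave 13. With fry 2 of 100 splits, the real one included, gave as many as 4 lists (highest other 4), so chance is not firmly excluded there. For gene-end windows all 100 of 100 splits gave at least the 0 windows of the real one (highest other 1), so chance is not excluded. For the 3 gene bodies 2 of 100 splits, the real one included, gave as many, and for the 3 tiles likewise 2 of 100. Such counts were rare, but in each case 1 other split called more than the real one, 13 bodies and 15 tiles. Counts of this size are therefore not particular to DP against DR, and chance is not firmly excluded. In addition, edgeR and limma called 0 bodies and limma 0 tiles. Those other splits, DP A, C and E with DR A and B for bodies and DP A, B, D and E with DR C for tiles, called several times the real count and point to a structure of the samples, for which no cause was tested.

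The beta cell list was lower and the stromal list higher in DP. A lower share of beta cells alone would raise the markers of every other cell type alike, and the stromal list mean rose by 1.45 more than the endothelial one on the log2 scale (0.53 ± 0.53 in DP, -0.92 ± 0.20 in DR, n = 5 each; exact permutation p = 0.00794), which argues against that as the whole cause. With the acinar list mean as a covariate the beta cell list kept a camera adjusted p of 0.000158 (5.46e-07 to 0.00391 over 15 settings at the preset correlation) and the stromal list of 4.18e-13 (up to 1.4e-09), which argues against acinar tissue as the whole cause at that correlation only. Without the covariate, an estimated correlation gave 0.595 for both lists and fry 0.141 for the beta cell list. A gain of stromal and immune cells, and a change in beta cells that goes with being diabetes-prone, stay open and may act together.

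Short transcripts had higher medians in DP, unevenly between libraries. The median log2 fold change was 0.93 for genes whose longest isoform is under 200 nt. Of these 488 genes 10 passed as higher and 10 as lower (limma). The median fell through 0.48, 0.20, 0.10 and 0.03 over the longer classes, and was -0.05 for the longest. In the class next to the shortest, the median deviation of a library was 0.437 in DP 16, 0.361 in DP 20 and 0.183 in DP 19. It was -0.046 in DP 18 and -0.122 in DP 17, against -0.377 to -0.12 in DR libraries. Fitting and removing a trend over length in each library left a median log2 fold change of 0.49 in the shortest class and 0.17 in the next. The removal also ended the call of the respiratory chain list (camera adjusted p = 0.569, 0.00273 to 0.569 over 15 settings at the preset correlation, and 0.595 with an estimated one). The mean difference of this list shrank from 0.16 (6.80 ± 0.07 in DP, 6.64 ± 0.05 in DR) to 0.05 (6.76 ± 0.05 and 6.71 ± 0.03; exact permutation p = 0.103), so such a trend may account for most of that rise. Ribosomal protein genes went from 32 of 78 higher to 16 of 78 (limma) and from a mean difference of 0.57 to 0.42 (exact permutation p = 0.00794), which argues against the removed part of the trend as the whole cause, and 20 of 57 of their pseudogenes were higher too. The part of the trend left over, reads shared with pseudogenes and a biological difference between DP and DR stay open and were not tested.

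In the trypsinogen cluster 6 genes rose while their neighbours did not pass. More acinar tissue would raise all acinar markers alike, but those that are not trypsinogens differed by 0.40 (8.60 ± 1.57 in DP, 8.20 ± 1.05 in DR, n = 5 each, mean log2(FPKM + 1)) against at least 6.71 for the 6 genes, which argues against it. Reads taken from the neighbours would lower these against other acinar markers, but as a set they were higher by 0.71 (exact permutation p = 0.00794). Prss2 went the way of this explanation, at -0.69 with the acinar list mean as a covariate (limma adjusted p = 0.00551, and 0.00291 to 0.996 over 16 settings). That list mean holds Prss1, Try4, Try5, Try10 and Prss2 itself. It differed by 0.83, against 0.40 for the acinar markers that are not trypsinogens, so part of the fall of Prss2 is built into the covariate. Reads taken from Prss2 stay open as a part of the rise. A sequence variant or copy number difference between the DP and DR mice that lets reads align to these copies, and a real change in their transcription, also stay open and were not tested.

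Of 282 groups of 5 samples examined, 20 (7.09%) had a sample far from the other 4, where chance gives about 1 in 20, and 7 of the 20 involved DP 16 and 5 involved DR 12. Each value is the gap to the nearest sample as a share of the group's range. DP 16 was apart in the beta cell list (0.724; mean log2 6.24, next 7.06), Pdx1 (0.738, lowest), Mest (0.746, highest), interferon response (0.875; 4.23, next 2.90), monogenic and type 2 diabetes genes (0.836, highest), endothelial markers (0.833, highest) and fatty acid oxidation (0.720, highest). DR 12 was highest in Car3 (0.994; 3.95, next 0.0247), adipocyte markers (0.820; 3.92, next 2.08), Gnmt (0.841), Saa3 (0.764) and Gc (0.711). DR 13 was highest in Ndufa1 (0.773) and Mest (0.711), DR 14 lowest in Derl3 (0.724) and highest in glycolysis (0.721), DR 11 lowest in Cib3 (0.748) and DP 17 highest in fatty acid and sterol synthesis (0.775). Among bisulfite samples DR C had the lowest share of autosomal CpGs covered (0.736; 32.3%, next 70.2%) and the highest share of reads on CpGs of over 100 reads (0.815; 10.6%, next 4.70%).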

How the results depend on the processing

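Rescaling over genes of at least 200 nt, the combination of leaving out DP 16 with the acinar covariate, removal of the length trend, the filters on HIDATA, FAIL and length, the less methylated gene end, leaving out CpGs of over 100 reads and tiles with at least 10 reads were chosen after seeing the data. The other settings were chosen before. The count of 2116 expression calls became 47 after rescaling to the same sum (27 of them among the 2116) and 1134 after rescaling over genes of at least 200 nt (977 of them). It was 4479 with array weights, 3270 without DP 16 and with the acinar covariate, and 734 to 3466 without single libraries. Under the other settings it lay between 1422 and 2462. In the sums used for rescaling 19.2% to 93.1% of FPKM fell on isoforms under 200 nt, and the cause of these changes was not tested. Single named genes were followed under up to 16 settings, which leave out both rescalings, array weights, the filters and single isoforms. Of 95 named genes past the threshold 39 passed under all of these, and none changed direction in them, while 6 of the 14 others passed under some. How the named genes fare under the settings left out was not examined. Of all 109 named genes 53 were weaker without DP 20 and 53 without DR 14, 45 without DP 19, 41 without DR 12, 40 without DR 15 and 5 without DP 16, where weaker means that the call was lost or that a gene not past the threshold changed sign. Prss2, which had not passed, reversed to -0.69 with the acinar covariate and to -0.67 with DP 16 left out as well. The 13 lists became 0 with an estimated correlation and 4 with fry, and 11 to 15 without single libraries. The global methylation difference of 0.052 points ran from -0.378 to 0.518 without single samples, never past the exact test. The 0 gene-end windows became 1 with 500 bp on each side and 0 to 1 without single samples. The 3 gene bodies became 0 with edgeR, 0 with limma and 34 with a global offset. The 3 tiles became 0 at 50 reads, 0 with limma, 9 in 5 kb tiles, 10 at 10 reads and 0 to 21 without single samples; at 50 reads 972 tiles were tested. The authors' 338 regions became 102 at an fdr under 0.01 and 223 with at least 5 sites, by construction of the stricter rule. The 0 genes changed in both measures became 589 at unadjusted p. For the other changes in methylation calls and lists the cause was not tested. Depth limits the methylation tests, since DR C held 0.554 reads per autosomal CpG and set which regions had 20 reads in every sample. The sample letters do not pair the bisulfite samples: deviations of same-lettered samples correlated at -0.024, -0.055, -0.021, 0.007 and -0.011 for A to E, and only D correlated best with its own letter. With the letter as a block the global difference was 0.052 (exact sign-flip p = 0.938), gene-end windows 0, gene bodies 2 and tiles 0. RNA sample numbers are not shared between groups.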

Other observations

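The genes and the tests in this part were chosen after the values were seen. Several genes that lie outside the lists also separated the groups completely. Chgb (chromogranin B), a gene of secretory granules, rose from 686 ± 71.5 to 1618 ± 414 FPKM (1.20; n = 5 each; limma, Benjamini-Hochberg adjusted p = 0.00698) and Nucb2 (nucleobindin 2) by 1.32 (limma adjusted p = 0.00467). Granule genes were not tested as a group, and of others Chga (-0.41, limma adjusted p = 0.327), Scg2 (0.07, 0.846) and Pcsk2 (0.02, 0.94) did not pass, and Slc30a8 fell. Also higher were single genes whose products act on new secretory proteins in the endoplasmic reticulum, which were not tested as a group: Sec11c, a signal peptidase subunit (0.93), the prolyl isomerases Fkbp11 (1.15) and Ppib (0.76), the peroxiredoxin Prdx4 (0.83) and the collagen chaperone Serpinh1 (1.09). Pomp, which helps to assemble proteasomes, rose by 0.93 (limma adjusted p = 0.000884), and Mt3, a metallothionein, by 2.01 (limma adjusted p = 0.00569), while Mt1 and Mt2 fell.

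Further single genes were lower. Pcx (pyruvate carboxylase), which refills the citric acid cycle, fell from 39.1 ± 1.58 to 18.6 ± 8.02 FPKM (-1.14; n = 5 each; limma adjusted p = 0.0196), and the phosphatase inhibitor Ppp1r1a by -1.14 (limma adjusted p = 0.0155). Th (tyrosine hydroxylase, -0.93), the receptor tyrosine kinase Ret (-0.88), the guidance receptor Robo2 (-1.08), the stress transcription factor Atf5 (-1.16) and the growth factor Vegfb (-1.03) fell. So did Cplx2 (-0.67), which takes part in vesicle fusion.

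A hypothesis from these values is that beta cell genes gained methylation in DP islets. At their gene-end windows 24 genes of the beta cell list averaged 44.1% ± 0.26 in DP and 40.7% ± 1.43 in DR (n = 5 each), 2.51 points more than all genes together, higher in 5 of 5 DP samples than in any DR sample (exact permutation p = 0.00794, the smallest possible; Benjamini-Hochberg adjusted over 24 lists 0.0953). In gene bodies 30 genes averaged 55.8% ± 2.90 and 53.4% ± 0.94, 2.32 points more, with 3 of 5 DP samples above all DR samples (exact permutation p = 0.0873; adjusted 0.571). Neither passed the adjustment, so the hypothesis stays open. If beta cells methylate these genes less than other cells do, a lower share of beta cells could give the same values and cannot be told apart here. The dedifferentiation list pointed the other way at its 6 gene-end windows, 42.4% ± 2.35 and 47.1% ± 3.28 (exact permutation p = 0.00794; adjusted 0.0953).

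A further hypothesis was that genes at the authors' regions change in expression more often. Of 196 expressed genes that overlap a region 27 changed (13.8%, against 14.4% of the others; Fisher's exact odds ratio 0.948, p = 0.918), and draws matched on the number of tested CpGs gave 28.3 on average (permutation p = 0.65), so no excess was seen.

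Reads covering CpGs of the Y chromosome were present in all 10 bisulfite samples of female mice, 6115 to 13903 per sample, with 71.4% (DP A) to 75.8% (DP D) methylated.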
